A study of Mus musculus with 32 samples.

How the data were processed

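The labels describe spinal cord samples of mice on a mixed background of FVB/N, C57BL/6 and DBA/2, either non-transgenic or carrying 12 copies of a CHMP2Bintron5 transgene. Per the labels, total RNA was extracted with Trizol and a column kit, and stranded poly(A)-selected libraries were made from 500 ng of RNA. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, mapped to mm10 with TopHat2 2.0.14 and Bowtie2 2.1.0, and counted per gene with HTSeq 0.6.1. The annotation release and the strand setting of the counting are not given in the sources used here.

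The deposited counts gave whole numbers for 45706 Ensembl gene identifiers in 32 libraries. Of these identifiers, 45143 had a symbol in the GRCm38 annotation, and the other 563 took 0.079% of all counts. Gene positions in GRCm38 and gene types came from the same annotation. The counts were the authors' own, and everything from here on was computed from them.

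Genes with too few counts were removed with the default filter of edgeR (filterByExpr, minimum count 10, minimum total 15), which left 20015 genes. Library sizes were scaled with TMM. A quasi-likelihood negative binomial model with 1 term per combination of genotype and age was fitted to all 32 libraries in edgeR 4.0.16. Each p was two-sided and was adjusted over the 20015 genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The comparisons were genotype at each of the 3 ages, the difference between the genotype effects of each pair of ages, and each pair of ages in controls, 9 in all. Values per gene are CPM, counts scaled to a common total, on TMM-scaled library sizes, as mean ± SD over libraries, and log2 fold changes are given ± SE of the model.

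Genes to be named were chosen by a rule fixed before the data were examined. For each genotype comparison it took Chmp2b, the 12 called genes with the highest and the 8 with the lowest log2 fold change, and up to 4 members of each gene list. The largest changes were taken among called genes with a mean of at least 1 CPM and with every CHMP2Bintron5 library on the same side of the control mean, leaving out gene models without a name. For the other comparisons the rule took 6 genes in each direction. Among the genes the rule named, those described are the ones whose call stood when each library was left out in turn, unless the dependence is stated. Thy1 and Chrna2 are discussed at every age, and genes outside the rule are marked where they appear.

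Gene lists were also fixed before the data were examined, from textbook knowledge of spinal cord cell types and of the pathways that a subunit of the ESCRT complex acts in. The 45 tested lists held 821 genes, of which 815 were found in the table. They covered neurons (general, motor, excitatory, inhibitory, sensory neurons of the dorsal root ganglion), synapse, axonal cytoskeleton and transport, axon injury response and immediate early genes. They covered glia (oligodendrocyte, oligodendrocyte precursor, astrocyte, reactive astrocyte, homeostatic and disease-associated microglia, Schwann cell, ependymal) and other cells (endothelial, pericyte and smooth muscle, meninges and fibroblast, perivascular macrophage and monocyte, T and NK, B and plasma, neutrophil, erythrocyte, adipocyte, skeletal muscle). Immune lists were complement, cytokines and chemokines, interferon response, Toll-like receptor signalling, and MHC class I and class II presentation. Metabolic and cellular lists were cholesterol synthesis, cholesterol efflux and oxysterols, fatty acid synthesis, sphingolipid metabolism, oxidative phosphorylation, lysosome, autophagy, ESCRT machinery, ALS and FTD genes, unfolded protein and integrated stress response, glucocorticoid response and cell cycle. A list of sex-linked genes was read per library and was not tested as a set.

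Each list was compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the 45 lists of a comparison. The same test with a correlation estimated from the data, and fry, a rotation test of whether a list's genes move on balance one way, were run beside it. For lists described at length the number of members called over all genes is given, in many cases with the number called when p was adjusted over the list alone. For lists not called the lowest adjusted p is given in most cases.

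Measures of single libraries, such as the share of mitochondrial counts, were compared between genotypes at each age by an exact permutation test of the difference in means, two-sided, over all ways of dividing the libraries. A self-test added changes of known size to simulated tables built like this one. At a 2-fold change the model recovered 89% of changed genes at 1.5 months, 86% at 6 months and 94% at 10-12 months, and between 74% and 78% of changed differences between ages. At a 1.5-fold change it recovered 64%, 55% and 68% for genotype and 26% to 41% for the differences.

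Added after the data were examined were a correction of each library for trends with GC content and gene length, by splines with 5 degrees of freedom available for 19914 of the tested genes, and fits without sets of libraries that stood apart. In a simulated table with a GC trend and a raised lysosome list, 8206 genes were called without this correction and 21 with it. The 21 may include genes of that list. The simulated trend was linear and the same in every library of a group, whereas the slopes of the real libraries varied within groups. Nothing in the labels says that the samples of a group came from separate animals. The p-values therefore measure only the spread between these samples.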

Results

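RNA from the spinal cord of CHMP2Bintron5 transgenic mice and of non-transgenic control mice was sequenced at 3 ages. CHMP2B is a subunit of ESCRT-III, the complex that closes off vesicles at endosomes, and CHMP2Bintron5 is a truncated form linked to frontotemporal dementia and amyotrophic lateral sclerosis. The samples address how the transcriptome of the cord differs with the transgene at 1.5, 6 and 10-12 months. There were 32 libraries, 17 from controls and 15 from CHMP2Bintron5 mice. Controls numbered 6 at 1.5 months, 5 at 6 months and 6 at 10-12 months, and CHMP2Bintron5 samples numbered 5, 4 and 6 at the same ages. The design text of the series gives 4 CHMP2Bintron5 samples at 1.5 months and an age of 12 months for the oldest group, and the sample labels were followed. Total counts per library ran from 28368376 to 85348326. In M counts they were 28.4 to 85.3 in controls and 42 to 64.1 in CHMP2Bintron5 at 1.5 months. They were 35.4 to 71 and 36.2 to 72 at 6 months, and 38.7 to 53.9 and 31.6 to 48.2 at 10-12 months.

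Some libraries stood apart from the rest, and their markers are given here as measured. CHMP2Bintron5 replicates 2 and 3 at 6 months held transcripts of dorsal root ganglion neurons, with Avil, an actin-binding protein of sensory neurons, at 59.9 and 146 CPM against at most 1.41 CPM in the other 30 libraries. Acta1, skeletal muscle actin, exceeded 30 CPM in 6 libraries. They were control replicate 2 and CHMP2Bintron5 replicate 3 at 1.5 months, control replicates 4 and 5 and CHMP2Bintron5 replicate 1 at 6 months, and CHMP2Bintron5 replicate 3 at 10-12 months. Control replicate 4 at 6 months had 3.279% of its counts on genes classed as similar to ribosomal RNA, against at most 0.262% elsewhere. Control replicate 5 at 6 months had 1120 CPM of Thy1, against 452 to 755 CPM in the other controls and 1320 to 1860 CPM in CHMP2Bintron5 libraries. CHMP2Bintron5 replicate 4 at 6 months had 4.81 CPM of Xist, an X-linked gene, against at least 760 CPM elsewhere.

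The share of counts on mitochondrial genes was lower in CHMP2Bintron5 at each age. It was 3.75 ± 0.35% (SD, n = 5) against 4.51 ± 0.61% (SD, n = 6) at 1.5 months (exact permutation p = 0.0455). At 6 months it was 3.49 ± 0.24% (SD, n = 4) against 4.43 ± 0.3% (SD, n = 5; exact permutation p = 0.00794), and at 10-12 months 3.51 ± 0.31% (SD, n = 6) against 4.75 ± 0.82% (SD, n = 6; exact permutation p = 0.00433). The TMM scaling factors were higher in CHMP2Bintron5 by 0.046 at each age (exact permutation p = 0.00649, 0.00794 and 0.00216). Fold changes between genotypes also followed GC content. In the 10% of genes with the lowest GC content, near 39%, the median log2 fold change was -0.12, -0.18 and -0.24 at the 3 ages. In the 10% with the highest, near 59.5%, it was 0.20, 0.24 and 0.31. Across genes, Spearman's rho between log2 fold change and GC content was 0.366, 0.396 and 0.521, and genes are not independent replicates. The mitochondrial share went with a library's slope on GC content (log2 per 10% GC) in some groups. Among controls at 10-12 months it was 3.76% at a slope of 0.21 and 6.1% at -0.41. In CHMP2Bintron5 at that age it was 3.51%, the group mean, at the highest slope of 0.454. The difference in share between genotypes was not tested apart from the GC trend.

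**Figure D1:**
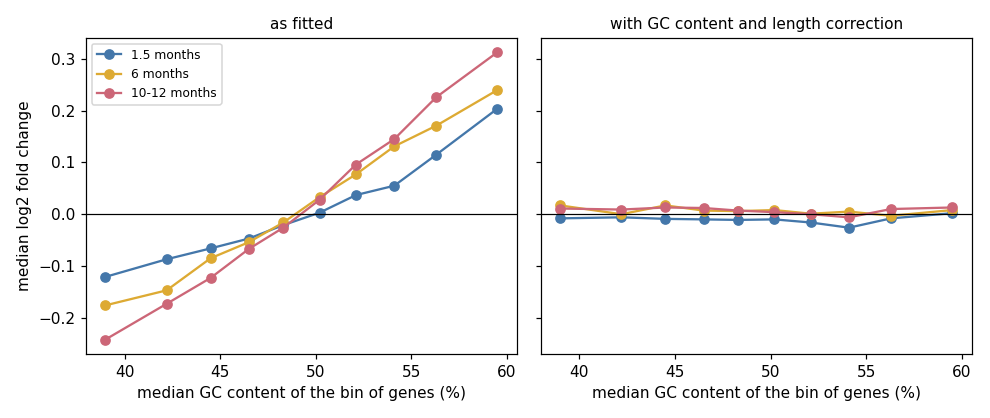
Median log2 fold change of CHMP2Bintron5 against control (y axis) in equal bins of the tested genes ordered by GC content in percent (x axis), as fitted on the left and with the correction for GC content and length on the right, with 1 line per age. The medians rise with GC content on the left, from -0.24 to 0.31 at 10-12 months, and lie near 0 on the right.

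The mouse gene Chmp2b was not called between genotypes at any age without a correction. Chmp2b (ENSMUSG00000004843, GRCm38 chromosome 16, 65539128 to 65562726, minus strand, protein-coding) had 81.7 ± 10.5 CPM (SD, n = 5) in CHMP2Bintron5 and 63.7 ± 7.6 CPM (SD, n = 6) in controls at 1.5 months. The log2 fold change was 0.36 ± 0.13 (SE; adjusted p = 0.142). At 6 months it had 65.7 ± 6.31 CPM (SD, n = 4) against 54.2 ± 14.7 CPM (SD, n = 5), and at 10-12 months 66.8 ± 8.73 CPM (SD, n = 6) against 56.1 ± 9.67 CPM (SD, n = 6), with adjusted p = 0.22 and 0.161. With the correction for GC content and length its log2 fold changes were 0.39, 0.38 and 0.41 and passed the test at each age (adjusted p = 0.00757, 0.0121 and 0.00191). Without control replicate 5 at 6 months the value at that age was 0.45 (adjusted p = 0.0374). The species of the transgene's cDNA is not given in the sources used here, and a count per gene does not tell how many of these reads came from the transgene.

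Thy1 and Chrna2 separated the genotypes at every age. Thy1 (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579, plus strand) encodes a surface glycoprotein of neurons and T cells. It was 2.55-fold higher at 1.5 months (1440 ± 98 CPM, SD, n = 5, against 566 ± 85.9 CPM, SD, n = 6; adjusted p = 7.03e-09) and 1.92-fold at 6 months (1510 ± 31.4, SD, n = 4, against 788 ± 190, SD, n = 5; adjusted p = 2.59e-05). At 10-12 months it was 2.41-fold higher (1530 ± 190, SD, n = 6, against 637 ± 71.9, SD, n = 6; adjusted p = 9.08e-09). The promoter of the transgene is not given in the sources used here, and reads from a transgene with Thy1 sequence would count toward Thy1. None of the other 14 members of the T and NK cell list changed at any age. Chrna2 (ENSMUSG00000022041, chromosome 14, 66135039 to 66152948, plus strand) encodes a nicotinic receptor subunit that marks Renshaw cells in the ventral cord. It was 4.95-fold lower at 1.5 months (0.644 ± 0.0984 CPM, SD, n = 5, against 3.21 ± 0.6 CPM, SD, n = 6). It was 4.1-fold lower at 6 months and 4.64-fold lower at 10-12 months, with adjusted p = 3.56e-10, 1.18e-07 and 2.48e-10. All 15 CHMP2Bintron5 libraries lay between 0.52 and 0.878 CPM and all 17 controls between 1.9 and 3.94 CPM.

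At 1.5 months, genes of activated microglia, complement and reactive astrocytes were higher in CHMP2Bintron5 cord, and genes of cholesterol synthesis and myelin were lower. Itgax (ENSMUSG00000030789, chromosome 7, 128129547 to 128150657, plus strand), an integrin subunit of activated microglia and dendritic cells, rose most among the named genes, 14.7-fold (8.03 ± 3.22 CPM, SD, n = 5, against 0.531 ± 0.191 CPM, SD, n = 6; adjusted p = 7.86e-08). Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912, minus strand), the intermediate filament of astrocytes, rose 2.12-fold from 1200 ± 123 CPM (SD, n = 6) to 2540 ± 132 CPM (SD, n = 5; adjusted p = 3e-08). Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260, plus strand), which makes the HMG-CoA used for sterols, fell 1.56-fold to 508 ± 91.8 CPM (SD, n = 5) from 793 ± 61.7 CPM (SD, n = 6; adjusted p = 0.000636). In all, 352 genes were higher and 394 lower, 97 and 29 of them by at least 2-fold.

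Of 25 genes of disease-associated microglia, 17 rose and none fell, and adjusted over the list alone 18 rose and 1 fell. The median log2 fold change was 0.76 and the list differed from other genes by camera (adjusted p = 7.49e-41). Besides Itgax these included Lgals3, a galectin, at 2.16 ± 0.21 (SE), and the pattern receptor gene Clec7a at 2.26 ± 0.28. Another was Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147, plus strand), a lipid-sensing receptor, at 1.84 ± 0.16. Of 16 genes of homeostatic microglia, 5 rose (6 adjusted over the list alone), among them the receptor gene Csf1r at 0.69 ± 0.09 (camera adjusted p = 5.89e-09). In the complement list 8 of 18 rose (8 adjusted over the list alone), such as C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882, minus strand) at 1.38 ± 0.14 and C1qb at 1.32 ± 0.17 (adjusted p = 1.7e-16). In the lysosome list 9 of 35 rose (13 rose and 1 fell adjusted over the list alone), such as the protease gene Ctsd at 0.69 ± 0.09 and Grn, which encodes progranulin, at 0.6 ± 0.1 (adjusted p = 2.81e-08).

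In the reactive astrocyte list 8 of 22 rose (12 rose and 1 fell adjusted over the list alone), with Ptx3, a pentraxin, at 1.56 ± 0.19 and Aspg at 1.41 ± 0.22 beside Gfap (camera adjusted p = 3.24e-11). In the axon injury response list 7 of 27 rose (13 rose and 1 fell adjusted over the list alone), led by the transcription factor gene Atf3 at 1.21 ± 0.2 (adjusted p = 9.69e-07). Of 13 excitatory neuron genes 4 rose (6 adjusted over the list alone; adjusted p = 5.87e-05). In the cholesterol synthesis list 8 of 25 fell (16 adjusted over the list alone), such as Cyp51, a sterol demethylase, at -0.49 ± 0.09 and Idi1 at -0.65 ± 0.13 (adjusted p = 3.98e-12). In the oligodendrocyte list 7 of 16 fell (7 adjusted over the list alone), such as Mobp, a myelin protein, at -0.48 ± 0.1 (adjusted p = 9.69e-07). In the fatty acid synthesis list 5 of 19 fell (8 fell and 1 rose adjusted over the list alone), such as Acss2 at -0.46 ± 0.06 (adjusted p = 0.000101). These 10 lists were the ones whose calls held with an estimated correlation, with adjusted p between 0.000163 and 0.0237. With the correction for GC content and length as well, the oligodendrocyte list did not hold (adjusted p = 0.0541 with an estimated correlation) and the sphingolipid list did (adjusted p = 0.0386).

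Another 12 lists were called at 1.5 months by camera with the preset correlation but not with an estimated one. By fry 20 lists were called at this age. Genes of axonal cytoskeleton and transport fell in 4 of 24 cases (7 adjusted over the list alone; adjusted p = 0.118 with an estimated correlation), such as Ina, a neurofilament subunit, at -0.48 ± 0.06. Synapse genes fell in 5 of 35 cases (8 fell and 1 rose adjusted over the list alone; adjusted p = 0.164 with an estimated correlation), such as Snap25, a subunit of the vesicle fusion complex, at -0.44 ± 0.09. Cytokine and chemokine genes rose in 4 of 22 cases (adjusted p = 0.0861 with an estimated correlation), among them the chemokine genes Ccl3 at 3.56 ± 0.42 and Ccl4 at 3.65 ± 0.35. MHC class II (3 of 13 rose), Toll-like receptor (2 of 22 rose, Tlr2 at 1.13 ± 0.14), motor neuron (2 of 20 rose) and general neuron genes (3 rose and 1 fell of 13) had adjusted p = 0.114, 0.112, 0.114 and 0.164 with an estimated correlation. Of the 12 general neuron genes other than Thy1, 2 rose and 1 fell, with a median log2 fold change of 0.04. Sphingolipid (4 of 36 fell, Fa2h at -0.39 ± 0.08), unfolded protein and integrated stress (3 of 27 fell) and oxidative phosphorylation genes (6 of 35 fell, Atp5b at -0.21 ± 0.04) had adjusted p = 0.0869, 0.141 and 0.61 with an estimated correlation. Endothelial and erythrocyte lists were called with no member changed, with adjusted p = 0.179 and 0.527 with an estimated correlation.

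Other named genes at this age were Atp2b1 (ENSMUSG00000019943, chromosome 10, 98914406 to 99026143, plus strand), which encodes a calcium pump of the plasma membrane, and Hapln1, a link protein of the perineuronal net. Atp2b1 was lower by 2.28-fold (77.5 ± 8.52 CPM, SD, n = 5, against 176 ± 29.4 CPM, SD, n = 6) and Hapln1 was at -1.15 ± 0.17. Slc6a5, the glycine transporter of inhibitory neurons, was at -0.65 ± 0.1, and Dio2, which activates thyroid hormone, at -1.22 ± 0.22. The number of genes called was 483 without CHMP2Bintron5 replicate 4, 489 without control replicate 5 and at most 819 without any 1 library. It was 308 when the libraries of this age were fitted alone, and 1671 with the correction for GC content and length, which kept 697 of the 746.

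**Figure D2:**
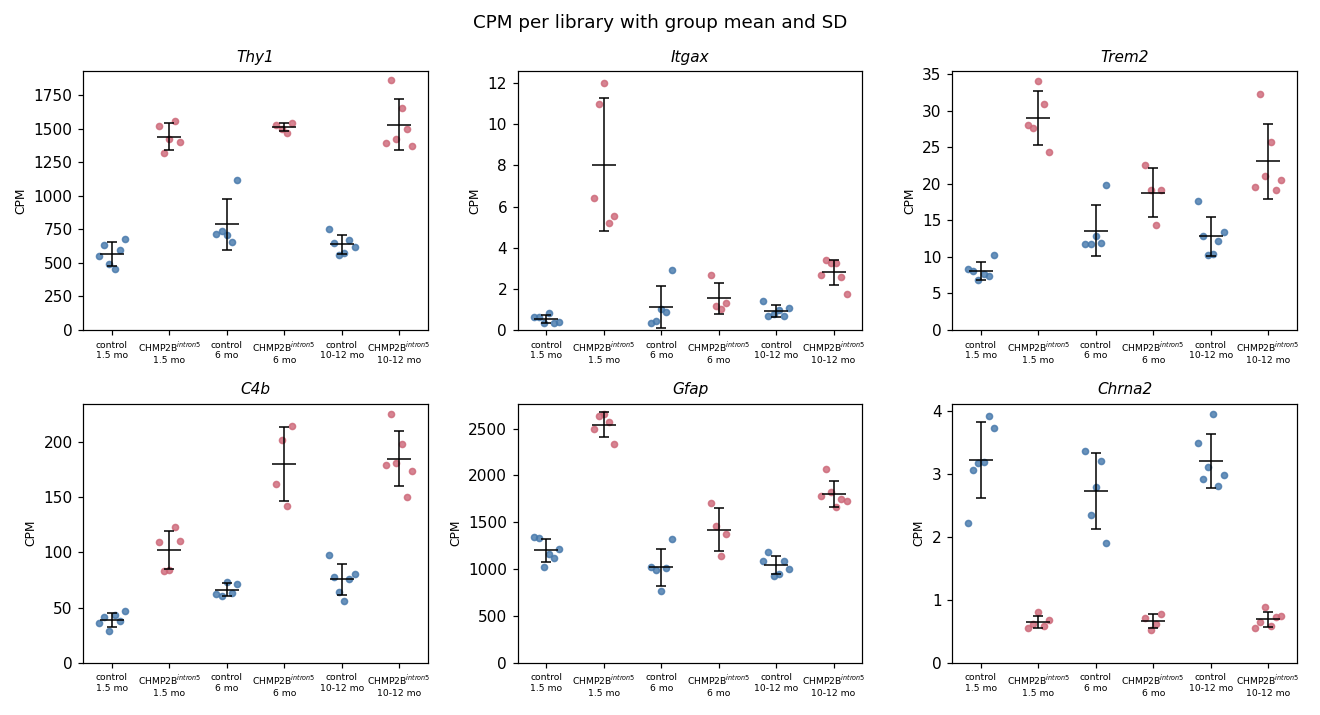
CPM (y axis) of 6 genes in each of the 32 libraries (points) by genotype and age (x axis), with black bars at the group mean and whiskers of 1 SD. Thy1 and C4b are higher and Chrna2 lower in CHMP2Bintron5 at each age, and Itgax lies near 8.03 CPM only in the CHMP2Bintron5 group at 1.5 months.

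At 6 months, genes of sensory neurons were higher in CHMP2Bintron5, with high values in 2 of its 4 libraries, and genes of myelin, axonal transport and endothelium were lower. None of these lists held with an estimated correlation (adjusted p = 0.17, 0.115, 0.175 and 0.115 with an estimated correlation), nor did they with the correction for GC content and length. Avil (ENSMUSG00000025432, chromosome 10, 127000709 to 127020994, plus strand) had 51.8 ± 68.4 CPM (SD, n = 4) against 0.83 ± 0.258 CPM (SD, n = 5). Its log2 fold change was 5.96 ± 0.83 (SE; adjusted p = 3.52e-05), and 0.12 (adjusted p = 0.854) without replicates 2 and 3. C4b was 2.73-fold higher (180 ± 33.6 CPM, SD, n = 4, against 66 ± 5.79 CPM, SD, n = 5; adjusted p = 8.91e-07). Kif5a (ENSMUSG00000074657, chromosome 10, 127225696 to 127263348, minus strand), a kinesin heavy chain that carries cargo along axons, was 1.38-fold lower (978 ± 107 CPM, SD, n = 4, against 1350 ± 26 CPM, SD, n = 5; adjusted p = 0.000333). In all, 1137 genes were higher and 1137 lower, 175 and 94 by at least 2-fold.

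Of 11 tested sensory neuron genes 10 rose (10 adjusted over the list alone), with a median log2 fold change of 2.41 (camera adjusted p = 3.33e-09; adjusted p = 0.17 with an estimated correlation). Among them the sodium channel gene Scn11a and the receptor gene Mrgprd, both of pain-sensing neurons, were at 7.64 ± 1.1 and 7.64 ± 1.17. Without replicates 2 and 3 none rose, 1 fell, and the median was 0.37 (adjusted p = 0.6). The highest-ranked named genes Pirt, Trarg1, Fxyd2, Trpv1, Tmem79, Asic3, Fam89a and Nmb lost their calls too, with adjusted p between 0.0903 and 0.955. Ctxn3 kept its call (1.66 ± 0.24, and 0.93 without the pair, adjusted p = 0.0154).

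**Figure D3:**
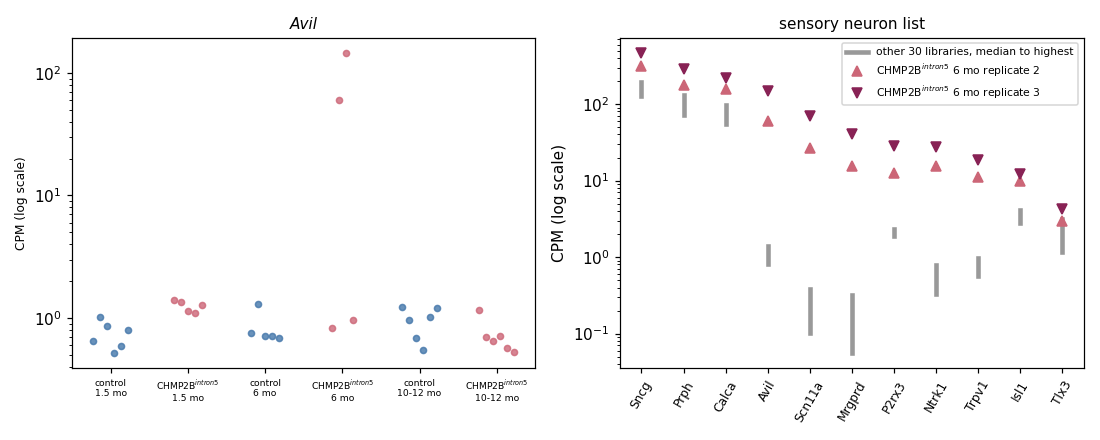
CPM on a log scale (y axes) of Avil in each library by group on the left, and of the tested members of the sensory neuron list on the right, with triangles for CHMP2Bintron5 replicates 2 and 3 at 6 months and grey bars from the median to the highest of the other 30 libraries. For 10 of the 11 members both triangles lie above every other library.

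The other lists called at 6 months lost their calls with an estimated correlation. By fry 13 lists were called at this age, as many as by camera with the preset correlation. In the oligodendrocyte list 6 of 16 fell (7 adjusted over the list alone), such as Mobp at -0.61 ± 0.11, with adjusted p = 0.115 with an estimated correlation. In the axonal cytoskeleton and transport list 11 of 24 fell and 1, Prph, rose (13 fell and 1 rose adjusted over the list alone; adjusted p = 0.175 with an estimated correlation). The kinesin genes Kif5a, Kif5b and Kif5c stood at -0.46 ± 0.08, -0.74 ± 0.13 and -0.55 ± 0.09, and Prph, a filament of peripheral neurons, was at 180 and 291 CPM in replicates 2 and 3 against at most 133 CPM elsewhere. Synapse genes fell in 11 of 35 cases and rose in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), such as Syt2, a calcium sensor of vesicle release, at -0.49 ± 0.08, and Vamp2 at 0.4 ± 0.05. Endothelial genes fell in 6 of 13 cases (6 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation), such as Pecam1, an adhesion protein, at -0.52 ± 0.09. Pericyte and smooth muscle genes fell in 4 of 11 cases (4 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation), such as Rgs5 at -0.83 ± 0.12.

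Fatty acid synthesis genes fell in 8 of 19 cases and rose in 1, such as the desaturase gene Scd2 at -0.44 ± 0.06, and cholesterol synthesis genes fell in 8 of 25, such as Sc5d at -0.86 ± 0.13. Their adjusted p were 0.115 and 0.344 with an estimated correlation. The axon injury response list had 7 of 27 genes higher (8 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), such as Sox11, a transcription factor of growing neurons, at 0.52 ± 0.1. The reactive astrocyte list had 4 of 22 (6 adjusted over the list alone; adjusted p = 0.344 with an estimated correlation), such as Amigo2 at 0.59 ± 0.07. Gfap was at 0.47 ± 0.11 (adjusted p = 0.00667) and at 0.31 with the correction for GC content and length, where it was not called (adjusted p = 0.106). MHC class I genes rose in 2 of 17 cases (8 rose and 1 fell adjusted over the list alone), such as H2-D1 at 0.56 ± 0.14 (adjusted p = 0.584 with an estimated correlation). Complement genes rose in 2 of 18 and oxidative phosphorylation genes fell in 6 of 35, with adjusted p = 0.566 and 0.693 with an estimated correlation. In the disease-associated microglia list 3 of 25 rose and 2 fell (adjusted p = 0.214), with Lgals3 at 1.17 ± 0.22 and Spp1, osteopontin, at -0.87 ± 0.17. Control replicate 5 of this age was high in Itgax (2.92 CPM, other controls 0.347 to 1.02) and Trem2 (19.8 CPM, other controls 11.7 to 12.8). Its values lower the contrast for these genes.

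Among genes named for the lowest values at 6 months, Rny3 and Rny1, short structural RNAs, were at -6.18 and -5.81, and at 0.24 (adjusted p = 0.842) and 0.06 (adjusted p = 0.946) without control replicate 4. The number of genes called at this age was 1305, 1418 and 1306 without control replicates 3, 4 and 5, 1286 and 939 without CHMP2Bintron5 replicates 3 and 4, and at most 2681 without any 1 library. It was 899 without CHMP2Bintron5 replicates 2 and 3, of which 776 were among the 2274, 1002 without the other 2 CHMP2Bintron5 libraries and 695 without the 6 libraries with Acta1 above 30 CPM.

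At 10-12 months, genes of disease-associated microglia and reactive astrocytes were higher in CHMP2Bintron5, and genes of axonal transport, synapse, endothelium and cholesterol synthesis were lower. Without the correction for GC content and length none of these lists held with an estimated correlation (adjusted p = 0.324, 0.216, 0.216, 0.357, 0.216 and 0.357 with an estimated correlation). By fry 16 lists were called at this age, as many as by camera with the preset correlation. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929, plus strand), a glycoprotein of lipid-laden phagocytes, was 4.67-fold higher (8.02 ± 3.19 CPM, SD, n = 6, against 1.72 ± 0.44 CPM, SD, n = 6; adjusted p = 8.92e-05). Lgals3 (ENSMUSG00000050335, chromosome 14, 47367751 to 47386160, plus strand) was 3.39-fold higher (18.1 ± 3.18 CPM, SD, n = 6, against 5.33 ± 1.89 CPM, SD, n = 6; adjusted p = 8.84e-07). Atp2b1 was 2.44-fold lower (72.8 ± 9.36 CPM, SD, n = 6, against 178 ± 23.6 CPM, SD, n = 6; adjusted p = 5.01e-09). Kif5b (ENSMUSG00000006740, chromosome 18, 6201002 to 6242174, minus strand) was 1.72-fold lower (282 ± 38.8 CPM, SD, n = 6, against 485 ± 58.8 CPM, SD, n = 6; adjusted p = 3.87e-05). In all, 1650 genes were higher and 2075 lower, 108 and 82 by at least 2-fold.

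Of 24 genes of axonal cytoskeleton and transport 11 fell (15 fell and 1 rose adjusted over the list alone), with Kif5a at -0.54 ± 0.07, Kif5c at -0.57 ± 0.08 and Ina at -0.44 ± 0.06. The list had adjusted p = 3.97e-07 by camera, adjusted p = 0.216 with an estimated correlation, and 0.0266 with that and the correction for GC content and length. Of 25 disease-associated microglia genes 11 rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 5.11e-05; adjusted p = 0.324 with an estimated correlation). Itgax was at 1.6 ± 0.36 and the growth factor gene Csf1 at 0.4 ± 0.07 in this list, and Spp1 was at -0.87 ± 0.14. In the reactive astrocyte list 8 of 22 rose (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.216 with an estimated correlation), with Gfap at 0.79 ± 0.1 and Aspg at 1.22 ± 0.21. Endothelial genes fell in 7 of 13 cases (7 adjusted over the list alone; adjusted p = 0.216 with an estimated correlation), such as Tek, a receptor for angiopoietins, at -0.68 ± 0.11 and Flt1 at -0.47 ± 0.07. Cholesterol synthesis genes fell in 10 of 25 cases (11 adjusted over the list alone) and oligodendrocyte genes in 5 of 16 (7 adjusted over the list alone), such as Cyp51 at -0.45 ± 0.08 and Mobp at -0.48 ± 0.1, with adjusted p = 0.357 and 0.24 with an estimated correlation.

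Synapse genes fell in 13 of 35 cases and rose in 3 (17 and 3 adjusted over the list alone; adjusted p = 0.357 with an estimated correlation), such as Snap25 at -0.56 ± 0.08 and Vamp2 at 0.31 ± 0.04. Axon injury genes rose in 10 of 27 cases (13 rose and 1 fell adjusted over the list alone; adjusted p = 0.216 with an estimated correlation), such as Atf3 at 0.87 ± 0.19 and Ecel1 at 0.85 ± 0.14. Interferon response genes fell in 7 of 30 cases (8 adjusted over the list alone), such as Ifi44 at -1.32 ± 0.33 and Gbp3 at -0.92 ± 0.22 (adjusted p = 0.717 with an estimated correlation). Fatty acid synthesis genes fell in 8 of 19 and rose in 1, such as Scd1 at -0.55 ± 0.09 (adjusted p = 0.216 with an estimated correlation). Oxidative phosphorylation genes fell in 10 of 35 cases, such as the cytochrome c gene Cycs at -0.4 ± 0.08 (adjusted p = 0.749 with an estimated correlation). Complement (4 rose and 1 fell of 18), cytokine and chemokine (3 of 22 rose), motor neuron (3 of 20 rose) and excitatory neuron genes (3 rose and 1 fell of 13) had adjusted p = 0.573, 0.473, 0.487 and 0.357 with an estimated correlation. The T and NK cell list was called with 1 of 15 members changed, Thy1, a protein of neurons as well (adjusted p = 0.674 with an estimated correlation). Lysosome genes rose in 9 of 35 cases and fell in 3 without a call for the list (adjusted p = 0.0504).

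**Figure D4:**
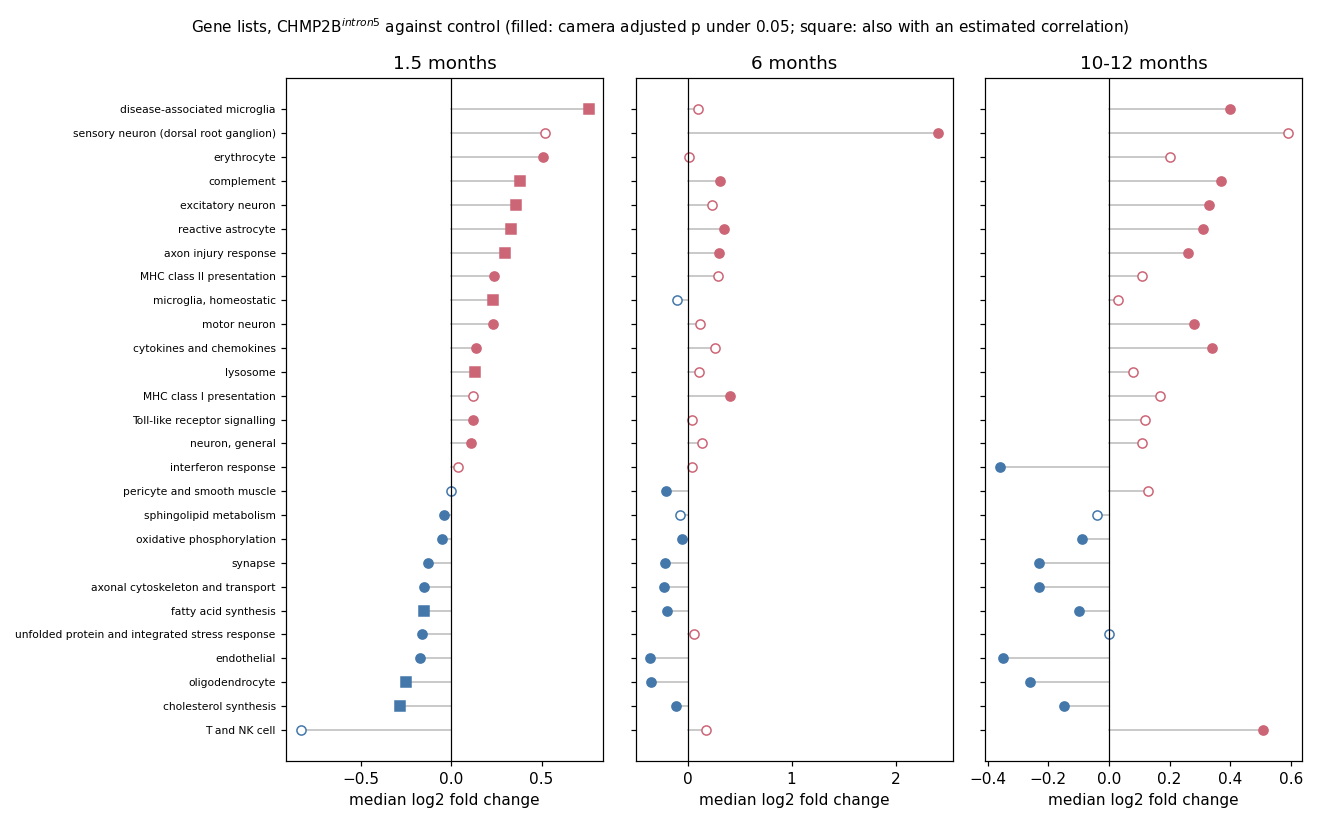
Median log2 fold change of CHMP2Bintron5 against control (x axes) of each gene list called at 1 or more ages (y axis), with a panel per age; filled symbols passed camera with the preset correlation and squares also with an estimated correlation. Squares occur at 1.5 months, for 10 lists, and at no other age.

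The number of genes called at 10-12 months was 2002 and 2205 without control replicates 3 and 4, 2253 and 2272 without CHMP2Bintron5 replicates 2 and 4, and at most 5012 without any 1 library. With the correction for GC content and length 3920 genes were called, of which 2514 were among the 3725.

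The remaining lists were called in no genotype comparison. Genes of the ESCRT machinery, the complex CHMP2B belongs to, numbered 26, of which 1 fell at 1.5 months, 1 rose at 6 months, and 1 rose and 3 fell at 10-12 months, including Chmp5 at -0.21 ± 0.05 (adjusted p of the list = 0.388, 0.892 and 0.782). Autophagy genes rose in 1, 2 and 2 and fell in 0, 0 and 9 of 26 cases (0.16, 0.322 and 0.111). Genes linked to ALS and FTD rose in 2 of 29 at each age and fell in 0, 3 and 6 (0.797, 0.69 and 0.29). The lowest adjusted p over the 3 ages was 0.0502 for skeletal muscle, 0.0504 for glucocorticoid response, 0.062 for Schwann cells, 0.0641 for cell cycle, 0.0641 for cholesterol efflux and oxysterols, 0.0652 for immediate early genes and 0.0652 for neutrophils. It was 0.0748 for oligodendrocyte precursors, 0.0983 for B and plasma cells, 0.121 for perivascular macrophages and monocytes, 0.187 for astrocytes, 0.258 for ependymal cells, 0.386 for meninges and fibroblasts, 0.612 for inhibitory neurons and 0.69 for adipocytes. Median and mean differed in sign, or from the test, for ALS and FTD genes (-0.05 and 0.02, test down) at 1.5 months. At 6 months they did so for the same list (-0.03 and 0.01, down), inhibitory neurons (0.07 and 0.02, down), erythrocytes (0.01 and -0.12, down) and Toll-like receptor genes (0.04 and -0.02, up). At 10-12 months they did for skeletal muscle (1.24 and 0.84, down), pericytes (0.13 and -0.01, down), B and plasma cells (0.01 and -0.09, down) and astrocytes (0.03 and -0.02, down).

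The same genes recurred between ages, which share no library. Between 1.5 and 6 months 106 higher and 260 lower genes were shared, where 20 and 22.4 were expected if calls were independent between ages. Between 6 and 10-12 months 657 and 870 were shared (93.7 and 118 expected), and between 1.5 and 10-12 months 187 and 316 (29 and 40.8 expected). The GC trend ran the same way at each age, so part of this sharing may come from it. With the correction for GC content and length the same pairs of ages shared 220 and 650 (50.2 and 93.7 expected), 874 and 1294 (142 and 193), and 343 and 762 (55.4 and 112). At all 3 ages 90 genes were higher, such as Thy1, C4b, Lgals3 and Gfap, and 250 were lower, such as Chrna2, Atp2b1, Ina and Mobp. With the correction for GC content and length 188 genes were higher and 608 lower at all 3 ages, 70 and 228 of them the same genes.

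The change of the genotype effect with age was tested as a difference of differences. Between 1.5 and 6 months the lower genes included microglial ones. Itgax had a difference of -3.42 ± 0.57 (SE; adjusted p = 0.00576), Mpeg1, a pore-forming protein of phagocytes, -1.77 ± 0.3 (adjusted p = 0.00576), and Fcrls, a receptor of resident microglia, -2.02 ± 0.33 (adjusted p = 0.00576). Control replicate 5 at 6 months had Itgax at 2.92 CPM, against 0.347 to 1.02 CPM in the other controls of that age, which enlarges the Itgax difference. Over the alternative fits it ran from -3.9 to -2.64. In the disease-associated microglia list 5 of 25 fell (14 adjusted over the list alone) and in the homeostatic list 3 of 16 (7 adjusted over the list alone), calls that held with an estimated correlation (adjusted p = 0.0011 and 0.000135). Control replicate 5 at 6 months was also high in the disease-associated genes Trem2 (19.8 CPM, other controls of that age 11.7 to 12.8) and Cd68 (10.9 CPM, others 5.44 to 6.58). The lists were not tested without this library. In all 15 genes were lower and 16 higher, the latter including the sensory neuron genes Trarg1 and Trpv1, at 4.95 ± 0.92 and 4.18 ± 0.77. These were not called without CHMP2Bintron5 replicate 3 at 6 months (3.57 and 3.26, adjusted p = 0.0842 and 0.0788). Of 45 lists 16 were called, 2 of them with an estimated correlation. Without CHMP2Bintron5 replicates 2 and 3 at 6 months no gene was called by edgeR for this difference, with Itgax at -3.07, Mpeg1 at -1.62 and Fcrls at -2.25 (adjusted p = 0.157, 0.157 and 0.052), and DESeq2 called 126 genes with all libraries.

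Between 6 and 10-12 months 1 gene, Avil, was called (-6.33 ± 1.06, SE), with 586 genes at an unadjusted p under 0.05 in edgeR, 19 genes called by DESeq2 and 0 by limma-voom. Without replicates 2 and 3 of CHMP2Bintron5 at 6 months Avil was at -0.49 and no gene was called. Of 45 lists 9 were called and those of sensory neurons (lower) and oligodendrocyte precursors (higher) held with an estimated correlation (adjusted p = 0.0281 and 0.0196). Neither held so with the correction for GC content and length (adjusted p = 0.0542 and 0.0521 with an estimated correlation), and without the pair the sensory neuron list had a median of 0.25 (adjusted p = 0.0666). Between 1.5 and 10-12 months 2 genes were called, both lower. They were Fcrls (-1.69 ± 0.3) and Pdcd1, an inhibitory receptor of T cells (-2.92), which is named because it was called and lies outside the rule for named genes. Of 45 lists 11 were called, and disease-associated and homeostatic microglia, both lower, held with an estimated correlation (adjusted p = 0.0204 and 0.00504). For 1.5 against 6, 6 against 10-12 and 1.5 against 10-12 months fry called 2, 0 and 2 lists, where camera called 16, 9 and 11.

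These counts rested on single libraries. For 1.5 against 6 months leaving out 1 library gave 10 to 130 genes. It gave 130 and 64 without CHMP2Bintron5 replicates 1 and 4 at 6 months, 10 without replicate 3 and 16 without replicate 2 of that group. It gave 16 to 20 without control replicates 1, 3, 4 or 5 at 6 months, 19 and 18 without control replicates 2 and 3 at 1.5 months, and 13 and 20 without CHMP2Bintron5 replicates 2 and 3 at 1.5 months. For 6 against 10-12 months it gave 0 to 39, with 28 and 39 without CHMP2Bintron5 replicates 1 and 4 at 6 months. It gave 0 without any 1 of the 5 controls or of CHMP2Bintron5 replicates 2 and 3 at 6 months, of control replicates 1, 2, 5 and 6 or of CHMP2Bintron5 replicates 2 to 6 at 10-12 months. For 1.5 against 10-12 months it gave 0 to 10, with 10 without control replicate 5 at 6 months, 4 without CHMP2Bintron5 replicate 2 at 10-12 months and 0 without control replicate 4 at 1.5 months. That count was 1 without any 1 of control replicates 1 to 3 and CHMP2Bintron5 replicates 2 to 5 at 1.5 months, control replicates 1 to 4 and CHMP2Bintron5 replicates 1 and 3 at 6 months, and control replicates 1, 2, 3, 5 and 6 and CHMP2Bintron5 replicates 1, 4, 5 and 6 at 10-12 months.

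**Figure D5:**
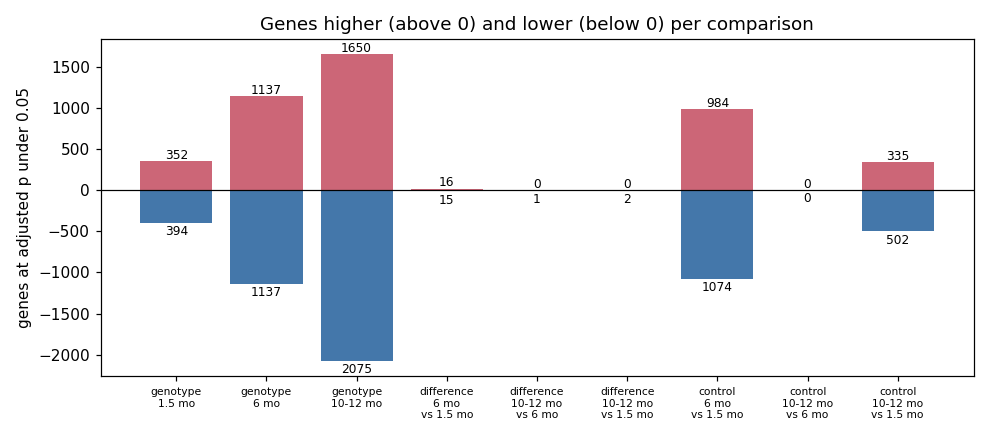
Number of genes at an adjusted p under 0.05 (y axis) in each of the 9 comparisons (x axis), with bars above 0 for higher and below 0 for lower genes. The genotype comparisons call 746, 2274 and 3725 genes, and the differences between ages 31, 1 and 2.

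Controls were also compared between ages, where anything else that the samples of an age shared goes with age. Between 1.5 and 6 months genes of myelin and of cholesterol synthesis were lower with age. Mal (ENSMUSG00000027375, chromosome 2, 127633226 to 127656695, minus strand), a membrane protein of myelin, fell 2.33-fold (536 ± 66.9 CPM, SD, n = 5, against 1250 ± 194 CPM, SD, n = 6; adjusted p = 6.12e-08). In the oligodendrocyte list 10 of 16 fell (12 adjusted over the list alone), such as Mog at -1.08 ± 0.1. In the cholesterol synthesis list 15 of 25 fell (16 adjusted over the list alone), such as Hmgcs1 at -0.93 ± 0.12 and Cyp51 at -0.8 ± 0.09. Both calls held with an estimated correlation (adjusted p = 0.000236 and 0.00281), and 10 other lists did not hold. Microglial and complement genes were higher with age, such as Lgals3 at 1.16 ± 0.21, Trem2 at 0.75 ± 0.16 and C4b at 0.76 ± 0.13. The lists of disease-associated microglia and complement had adjusted p = 0.34 and 0.293 with an estimated correlation. In all 984 genes were higher and 1074 lower, and 1426 higher and 1000 lower without the 6 libraries with Acta1 above 30 CPM, with 1420 of the 2058 among them. The count was 1147 without control replicate 3 at 1.5 months, 1355, 1322 and 1154 without control replicates 1, 2 and 3 at 6 months, at most 2933 without any 1 library, and 3613 with the correction for GC content and length. Rny1 and Mir6240, named for the highest values (6.87 and 4.16), were at 0.98 (adjusted p = 0.0885) and 0.24 (adjusted p = 0.802) without control replicate 4 at 6 months.

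From 1.5 to 10-12 months in controls the lists of cholesterol synthesis and oligodendrocytes were lower again. Cholesterol synthesis genes fell in 19 of 25 cases (23 adjusted over the list alone), such as Hmgcs1 (355 ± 32.9 CPM, SD, n = 6, against 793 ± 61.7 CPM, SD, n = 6), and oligodendrocyte genes in 10 of 16 (11 adjusted over the list alone). Oligodendrocyte precursor genes fell in 3 of 13 cases, such as Gpr17, a receptor of maturing precursors, at -1.46 ± 0.17, and fatty acid synthesis genes fell in 5 of 19 and rose in 1. These 4 of 18 called lists held with an estimated correlation (adjusted p = 1.33e-06, 1.33e-06, 0.00212 and 0.0366), the last of them not with the correction for GC content and length (adjusted p = 0.0507 with an estimated correlation). Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706, plus strand), a fibrillar collagen, fell 3.67-fold (31.2 ± 4.9 CPM, SD, n = 6, against 114 ± 22.9 CPM, SD, n = 6). The meninges and Schwann cell lists had adjusted p = 0.3 and 0.292 with an estimated correlation. For sphingolipid genes median, mean and test were 0.02, -0.06 and down. In all 335 genes were higher and 502 lower. The total was 540 without control replicate 3 at 1.5 months, 553 without control replicate 6 at 10-12 months and at most 1037 without any 1 library. It was 438 when the groups were fitted alone, 1271 by DESeq2 and 2068 with the correction for GC content and length.

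Between 6 and 10-12 months no gene was called in controls by edgeR, where 954 had an unadjusted p under 0.05. DESeq2 called 7 genes and limma-voom 0, and leaving out 1 library gave up to 4, the highest without control replicate 3 at 6 months, and 2 without any 1 of control replicates 1, 2 and 5 and CHMP2Bintron5 replicate 4 at that age. It gave 1 without CHMP2Bintron5 replicate 5 at 1.5 months, CHMP2Bintron5 replicate 1 at 6 months, control replicate 1 at 10-12 months or CHMP2Bintron5 replicates 1 or 6 at 10-12 months. The Schwann cell and cholesterol synthesis lists were lower among the 8 called lists, and none of them held with an estimated correlation (adjusted p = 0.176 and 0.155) or was called by fry.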

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

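The tests of the GC trend, of the sensory neuron transcripts and of control replicate 5 at 6 months were chosen after the result was seen, and the tests on other splits of the samples were planned.

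Differences between ages in the genotype effect were taken up because the test of the difference itself passed. For 6 against 1.5 months 31 genes were called, with Itgax at -3.42, Ccl3, a chemokine, at -3.19, Clec7a at -2.2, Fcrls at -2.02, Mpeg1 at -1.77 and Cd180, a receptor of myeloid and B cells, at -1.53. Among higher genes were Avil at 5.2, Trarg1 at 4.95, Acpp at 4.74, Pirt at 4.55, Trpv1 at 4.18 and Ppp1r1c at 3.95. Leaving out 1 library ended the call of Cd180 in 22 cases, of Ppp1r1c in 23, of Avil in 14, of Pirt in 6, of Ccl3 in 4, of Acpp in 2 and of Clec7a in 2. Over the alternative fits Ccl3 ran from -3.5 to -2.13 and Clec7a from -2.37 to -1.48. Control replicate 5 at 6 months, with Ccl3 at 1.9 CPM against a mean of 0.293 CPM in the other controls of that age, enlarges the Ccl3 difference. For 10-12 against 6 months 1 gene was called, Avil at -6.33, which lost its call in 16 cases. For 10-12 against 1.5 months 2 genes were called, Fcrls at -1.69, which lost its call in 23 cases, and Pdcd1 at -2.92, which lost it in 1 case.

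Values of 15 measures were tested in each group for 1 sample far from the others. The measures included genes such as Avil and Rny1, whose changes rested on few libraries. The number found can therefore not be set against a rate expected by chance. Of 90 groups of values tested, 12 had a sample that stood out. Control replicate 5 at 6 months did so in Thy1 (1120 CPM, others 658 to 740), Itgax (2.92, others 0.347 to 1.02) and Trem2 (19.8, others 11.7 to 12.8). Control replicate 4 at 6 months did so in Rny1 (217 CPM, others 0.473 to 1.1) and in its total of 71 M counts (others 35.4 to 45.6 M), and control replicate 2 of that age in Avil (1.29 CPM). Among CHMP2Bintron5 libraries at 6 months, replicate 1 was far from the others in Itgax (2.66 CPM, others 1.02 to 1.29) and replicate 4 in Atp2b1 (63.9 CPM, others 75.7 to 76.9). At the other ages CHMP2Bintron5 replicate 4 at 1.5 months was far in Atp2b1 (63.1 CPM), control replicate 5 at 1.5 months in Gpnmb (0.803 CPM), and CHMP2Bintron5 replicates 1 and 5 at 10-12 months in Avil (1.16 CPM) and Rny1 (1.24 CPM).

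Other splits of the samples into groups of the same sizes were drawn, 100 for each comparison with the real one included. For genotype at 1.5 months (746 genes) 2 of the 100 splits, the real one included, gave as many. Chance as a source of the calls is not excluded there, because another split called far more. That highest other split called 3144, several times the real count, which points to a structure of the samples. The mean slopes on GC content (log2 per 10% GC) differed by 0.368 between the groups of that split, against 0.149 for the real groups and a median of 0.111 over the other splits. No other drawn split gave as many calls for genotype at 6 months (2274, highest other 2109) or at 10-12 months (3725, highest other 2462). The same held for controls at 6 against 1.5 months (2058, highest other 731) and at 10-12 against 1.5 months (837, highest other 52). The real genotype groups differed in GC slope by 0.219 at 6 months and 0.282 at 10-12 months. Those of the highest other splits differed by 0.276 and 0.324, with medians over the other splits of 0.079 and 0.122. The splits therefore argue against chance at these ages but do not separate genotype from the GC trend. For the differences the splits exchanged ages within each genotype, so genes that change with age alone were mixed within the groups drawn. They therefore cannot decide whether chance gave the 31 genes for 6 against 1.5 months (highest other 26). The same holds for the 2 genes for 10-12 against 1.5 months (highest other 16), where 3 of the 100 splits, the real one included, gave as many. Chance cannot be excluded for the difference of 10-12 against 6 months, where 14 splits gave at least the 1 gene called and the highest gave 10. For controls at 10-12 against 6 months 0 genes were called, so all 100 splits had to give as many, the highest 8. That test could decide nothing.

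Fold changes between genotypes followed GC content at each age, and a GC and length bias of the libraries may account for part of the calls. As the whole cause it was argued against, since 67.5% of the genes called at 10-12 months kept their call and sign after the correction, as did 93.4% at 1.5 months and 86.4% at 6 months. The slopes of the libraries on GC content differed by genotype (permutation p = 0.0059, genotype labels permuted within age), with no test passed at an age alone (exact permutation p = 0.344, 0.0873 and 0.0606), so bias and genotype overlap in part. Whether the slopes come from library preparation, from RNA quality or from the tissue stays open, and a biological shift with genotype was not tested apart from it. For Gfap at 6 months the correction ended the call, with a log2 fold change of 0.47 ± 0.11 (SE) before and 0.31 after.

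The sensory neuron transcripts in CHMP2Bintron5 replicates 2 and 3 at 6 months may come from dorsal root ganglion cells left on the dissected cord. Of the 11 tested members 10 lay above every other library in both, and the ratio of replicate 3 to replicate 2 in the excess ran from 1.34 to 2.62 (median 1.94). An effect of the CHMP2Bintron5 genotype of the size seen in the pair was argued against by the other libraries of the group. Without the pair the median log2 fold change of the list was 0.37 and the list was not called. A smaller effect cannot be excluded with so few libraries left, where members ran from -0.74 (P2rx3) to 0.79 (Calca). Its most abundant members, Sncg at 311 and 468 CPM, Prph at 180 and 291 CPM and Calca at 158 and 219 CPM, were also found in the other libraries, and how the cords were dissected is not given in the sources used here.

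Control replicate 5 at 6 months lay between the genotypes in several genes, as in Thy1 at 1120 CPM and Chrna2 at 1.9 CPM. On a scale from the other controls (0) to the CHMP2Bintron5 libraries (1) its median position over 22 genes called with at least 2-fold at both other ages was 0.29 (quartiles -0.1 to 0.53), against -0.21 to 0.05 in the other controls and 0.82 to 1.16 in CHMP2Bintron5 libraries. A CHMP2Bintron5 animal under a control label was argued against by that position. RNA of a CHMP2Bintron5 sample mixed into it cannot be told apart from variation between controls, since 59.1% of the genes lay above 0.1 against 18.2% to 45.5% in the other controls, and the spread of single genes keeps it open. Without this library 1306 genes were called at 6 months in place of 2274.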

How the results depend on the processing

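The correction for GC content and length and the fits without named sets of libraries were chosen after the data were seen, and the other alternatives were planned. Of 271 results of single genes, 175 kept direction and call in every alternative and 96 lost the call in at least 1, 53 of them without a single library, while 5 reversed. By alternative, calls were lost in 1 with RLE scaling, 2 with upper-quartile scaling, 13 without a filter, 0 with a filter of 1 CPM in 4 libraries (262 results with a value), 0 with DESeq2 (267), 29 with limma-voom, 45 with only the groups compared (268), 68 with a replicate block (220) and 2 with the GC correction. They were lost in 39 (and 3 reversed) without the 2 libraries with sensory neuron transcripts, 16 without the other 2 of that group and 32 (and 2 reversed) without the 6 with muscle transcripts. A covariate for sex was not run, since no library had more than 3 counts of the Y-linked genes. Replicate numbers did not pair the libraries (best correlation with the own number in 1 of 5, 0 of 4 and 1 of 6 pairs). The median of all genes moved by at most 0.1 (log2) in the alternatives other than the replicate block and single libraries left out, for which it was not computed. The cause was not tested where none is given.

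Genotype counts at 1.5, 6 and 10-12 months were 353, 758 and 1411 at an adjusted p of 0.01, 126, 269 and 190 with a 2-fold limit besides. They were 276, 302 and 1724 with the replicate block, which uses up degrees of freedom and keeps only replicate numbers found in both genotypes of an age. It thus left out control replicate 6 at 1.5 months and control replicate 5 at 6 months. At 1.5 months the count was 308 with only the groups compared (fewer samples) and 1671 with the GC correction. At 6 months it was 899 without the 2 libraries with sensory neuron transcripts, 1002 without the other 2 of that group and 695 without the 6 with muscle transcripts (fewer samples). Counts of differences, for 6 against 1.5, 10-12 against 6 and 10-12 against 1.5 months, were 126, 19 and 21 with DESeq2, 3, 0 and 7 with only the groups compared, 0, 0 and 0 with the block, 73, 4 and 14 with the GC correction. They were 0, 0 and 1 without the 2 libraries, 248, 172 and 1 without the other 2, and 10, 4 and 0 without the 6. They were 9, 0 and 0 at an adjusted p of 0.01. The first was 20 and the second 4 without a filter, and the second was 0 with limma-voom, 4 with upper-quartile scaling and 4 with the CPM filter. In controls, 6 against 1.5 and 10-12 against 1.5 months gave 606 and 365 at 0.01, 240 and 145 with the 2-fold limit, and 3613 and 2068 with the GC correction. The latter gave 438 with only the groups compared and 1271 with DESeq2. For 10-12 against 6 months controls gave 7 with DESeq2, 5 without a filter and 1 without the other 2 libraries.

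Lists called with an estimated correlation were 10, 0 and 0 at the 3 ages. Fry called 20, 13 and 16 lists, where camera with the preset correlation called 22, 13 and 16. In controls fry called 16 and 19 lists for 6 against 1.5 and 10-12 against 1.5 months, where camera called 12 and 18. Chmp2b stood at 0.39, 0.38 and 0.41 with the GC correction, where it passed. Genes shared between 1.5 and 6 months were 220 higher and 650 lower with the GC correction, 41 and 92 with only the groups compared, 52 and 168 without a filter, 48 and 133 without the other 2 libraries, 34 and 126 without the 6, and 54 higher without the 2. Between 6 and 10-12 months they were 428 higher with only the groups compared, 406 higher without a filter, 323 and 391 without the 2 libraries, 259 and 259 without the other 2 and 184 and 243 without the 6. Between 1.5 and 10-12 months they were 343 and 762 with the GC correction, 85 and 116 with only the groups compared and 123 higher without a filter. Reversed were Avil (-0.65), Pirt (-0.46) and Ppp1r1c (-0.24) in the difference of 6 against 1.5 months without the 2 libraries, which hold their signal. Reversed too were Rny3 and Rny1 at 6 months, at 0.19 and 0.12 without the 6 libraries and 0.24 and 0.06 without control replicate 4, which held them (-6.5 to 0.24 and -6.13 to 0.06 over libraries left out).

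Leaving out 1 library at a time gave 483 to 819, 939 to 2681 and 2002 to 5012 genes for genotype at the 3 ages, 10 to 130, 0 to 39 and 0 to 10 for the differences. It gave 1147 to 2933, 0 to 4 and 540 to 1037 for controls at 6 against 1.5, 10-12 against 6 and 10-12 against 1.5 months. Chmp2b was at 0.32 to 0.43, 0.21 to 0.45 and 0.2 to 0.32 at the 3 ages. Simulated 2-fold changes were recovered in 86% to 94% of genes for genotype and in 74% to 78% for differences, which limits what the differences can show.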

Other observations

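Some gene families with members of low or high values in CHMP2Bintron5 cord lie outside the fixed lists. Of 14 families examined 6 are described. They were chosen after values of their members were seen, so the counts describe these genes and test nothing. Of 13 perineuronal net components, the matrix around some neurons, 4, 4 and 5 were called lower at 1.5, 6 and 10-12 months and none higher. With the correction for GC content and length 5, 6 and 5 were lower and 0, 0 and 2 higher. Without the correction, the shares called over all genes would give 0.256, 0.738 and 1.35 lower. Acan, the aggrecan core protein, was at -0.78 ± 0.1 (SE), -0.86 ± 0.11 and -0.84 ± 0.09, and Hapln1 (ENSMUSG00000021613, chromosome 13, 89539796 to 89611652, plus strand) at -1.15 ± 0.17, -1.12 ± 0.19 and -1.28 ± 0.16. Of 90 potassium channel genes 9, 9 and 16 were lower and 4, 9 and 13 higher, and with the correction 15, 16 and 24 were lower and 5, 10 and 9 higher. Without the correction, the shares over all genes would give 1.77, 5.11 and 9.33 lower and 1.58, 5.11 and 7.42 higher. Kcna1 and Kcna2, channels of the axon next to the node, were at -0.6 ± 0.09 and -0.52 ± 0.08 at 1.5 months, -0.76 ± 0.1 and -0.67 ± 0.09 at 6 months and -0.74 ± 0.09 and -0.63 ± 0.07 at 10-12 months.

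Of 9 calcium-pumping ATPases 3, 4 and 4 were lower at the 3 ages and none higher, among them Atp2b1 at -1.19, -1.12 and -1.29. With the correction 3, 5 and 5 were lower and 1 higher at each age. Of 23 mitochondrially encoded genes 3, 7 and 15 were lower and none higher, with 7, 6 and 10 lower after the correction, beside the lower mitochondrial share of counts. Of 26 calcium channel genes 2, 5 and 10 were higher and 2, 2 and 3 lower, and with the correction 3, 8 and 7 were higher and 4, 5 and 5 lower. Of 21 GABA and glycine receptor genes 1, 5 and 5 were lower and 0, 2 and 2 higher, and with the correction 2, 6 and 4 were lower and 2, 2 and 1 higher. Without the correction, the shares over all genes would give 0.177, 0.511 and 0.933 lower ATPases and 0.453, 1.31 and 2.38 lower mitochondrial genes. For calcium channels they would give 0.457, 1.48 and 2.14 higher and 0.512, 1.48 and 2.7 lower. For GABA and glycine receptors they would give 0.413, 1.19 and 2.18 lower and 0.369, 1.19 and 1.73 higher.

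CHMP2Bintron5 replicate 4 at 6 months had 4.81 CPM of Xist, against 760 to 1390 CPM in the other 31 libraries. It also had lower values of genes that escape X inactivation, with Kdm6a at 33.4 CPM (44.1 to 73.8 elsewhere), Ddx3x at 183 CPM (210 to 495), Eif2s3x at 95.8 CPM (131 to 234) and Kdm5c at 48.2 CPM (50.2 to 79.3). Over 368 other X-linked genes its median deviation was -0.01 (log2). Counts of the Y-linked genes Ddx3y and Eif2s3y were at most 3 and 2 in any library.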
